A study of Rattus norvegicus with 18 samples.

How the data were processed

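Left ventricles of 18 male rats were studied, 6 each of WKY, ZSF1 lean and ZSF1 obese animals. Per the labels' protocols, total RNA was isolated with a Qiagen RNeasy kit, polyadenylated RNA was selected with a stranded TruSeq mRNA kit and single reads were sequenced on a HiSeq instrument. Per the submitters' processing notes, the genome build was Rnor_6.0 and the tools were HISAT2 2.1.0, HTSeq 0.11.2 and DESeq2 1.22.2. Their order, their settings, the strand setting of the counting and the treatment of reads that fit several genes are not given in the sources used here. The rats of different groups share no replicate numbers, and their batch entry names a type of RNA, the same for all. Library and sequencing batches are not given in the sources used here, so batch and group cannot be told apart.

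Only the authors' 3 lists of changed genes were used, with 5700 genes for ZSF1 obese against ZSF1 lean, 5709 for ZSF1 obese against WKY and 233 for ZSF1 lean against WKY. Per the file headers, each row gives an Ensembl gene identifier, a symbol, a description, a linear fold change and a false discovery rate. The fold, a ratio of the first group to the second, and the FDR, an adjusted p-value, are the authors' deposited values, and both columns were used as they stand. All listed genes had a fold of at least 2 or at most 0.5 and an FDR under 0.05, as tested on the values. The folds of the obese lists are powers of 2 with exponents rounded to 2 decimals, and those of the lean list were rounded to 2 decimals. An FDR was given as 0 for 17 genes in obese against lean and for 4 in obese against WKY.

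No read counts, mean levels, standard errors, unadjusted p-values or values per rat were used here. Depth per sample is therefore unknown, and the authors' adjusted p-value is the sole measure of error for a gene. It reflects the spread between the 6 rats of each group in the authors' fit. Values per rat, left-out rats, regrouped labels and the search for unusual samples or batches need per-rat data and were not run. Symbols on more than 1 identifier (10 in obese against lean, 11 in obese against WKY) were counted once per identifier. Genes with near-identical copies, such as ribosomal proteins, haemoglobins, small nucleolar RNAs and the RT1 genes, are uncertain.

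The log2 of each fold was computed from the deposited values. The 29 gene lists, the 12 lists of cell type markers and the rule for named genes were fixed before the data were examined. Named genes are, per comparison, the 8 largest rises and 8 largest falls, the 5 smallest adjusted p-values in each direction, up to 4 members per list by adjusted p, and 17 anchors, leaving out predicted and clone names. A minimum mean level could not be applied. Genes named outside the rule, after their values were seen, are Bcat1, Fgf21, Bnip3l, Trdn, Il1b, Myl7, Cnn1, Maoa, Rpl3l, Dbp, Bhlhe41, Nfil3 and, in the obese comparisons, Spp1 and Slc4a1. Some genes that the rule or the lists cover are not reported here by name.

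The planned list test, cameraPR on a Wald statistic with all tested genes as background, could not be made from lists of changed genes. In its place, the number of listed members that rose and fell was set against that of all other listed genes of the same comparison in a two-sided Fisher's exact test, a choice made after the tables had been read. Lists with at least 3 listed members were tested, 40 of 41 in each obese comparison and 2 of 41 in lean against WKY, with Benjamini-Hochberg adjustment within a comparison. The test asks whether changed members of a list lean one way. It treats genes as independent, which they are not, and the correlation between genes could not be estimated without values per rat. Some genes are in several lists, such as Cpt1b and Hadhb in those for fatty acid oxidation and PPAR targets. Lists that passed are therefore not independent of each other. A count adjusted over the list alone needs unadjusted p-values and was not made. Denominators are the list symbols found in the tables or in the reference. The median of each list was placed among 10000 random lists of the same size drawn from the same table, without matching on mean level. As alternatives, limma's cameraPR was run on log2 folds with preset correlations of 0.01 and 0.05, by ranks, and on the signed logarithm of the adjusted p.

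Fisher's test was tested on simulated data made by shuffling the log2 folds of the obese against lean table (5700 genes) and of the obese against WKY table (5709 genes). Where all members of a list fall, the call follows from the counts alone: lists of 8, 12 or 20 listed members pass in both and lists of 3 or 5 do not. With members that each fell with a chance of 80%, added after the results had been seen, 5% of lists of 8, 30% of lists of 12 and 55% of lists of 20 were called in the first table and 5%, 32.5% and 60% in the second, so lists of mixed direction are often missed. Of lists with random direction, 0.167% and 0.333% were called. A list with 5 or fewer listed members can therefore not be expected to pass. In the same kind of simulation, cameraPR with a preset correlation of 0.01 found 25% of lists of 8 and 100% of lists of 20 in both tables.

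The 3 tables were joined on the Ensembl identifier. The lean against WKY change implied by the obese tables is the difference of their log2 folds, without a standard error and hence without a test. Overlap was set beside the product of the list sizes over the number of genes listed in either table, and beside simulated unchanged groups that share the obese group. Simulated covariance needs the spread of values and was not computed, and the obese hearts cannot be divided without values per rat. A gene table of the GRCr8 assembly was used for names, neighbours and gene spans, and none of its coordinates are printed because the build differs. Gene span is the length of a gene on the genome, introns included, and stands in for transcript length, which was not used. Symbols matched for 93.1%, 93.3% and 88.8% of the genes in the 3 lists. Alternative settings were an adjusted p of 0.01, genes with regular names, a fold of at least 4, a common limit on the adjusted p and the list test variants.

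Scripts ran in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1. Permutation tests used 100000 resamples and were two-sided for differences.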

Results

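Polyadenylated RNA of the left ventricle was sequenced from 18 male rats in 3 groups of 6. Wistar Kyoto rats (WKY) were the control strain. ZSF1 lean rats were the hypertensive group, and ZSF1 obese rats, which have hypertension together with metabolic syndrome, were the group used as a model of heart failure with preserved ejection fraction. The series title places the question in mitochondrial function and metabolism. The data used here are the authors' lists of changed genes for the 3 pairs of groups, each gene with a fold change and an adjusted p-value from a comparison of 6 rats with 6. Levels per rat, standard errors and the genes that did not pass are not part of these lists, so sequencing depth is unknown, and a gene absent from a list cannot be told from one that was not detected.

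The first comparison, ZSF1 obese against ZSF1 lean, asks what differs in the heart when metabolic syndrome is added to hypertension. The authors' deposited table held 5700 genes, of which 3045 rose and 2655 fell in the obese hearts. Among listed genes, nuclear genes of mitochondrial energy metabolism and genes of the sarcomere and calcium handling mostly fell, the 12 listed mRNAs of the mitochondrial genome rose, and genes of the extracellular matrix, inflammation and antigen presentation rose. Among the listed genes the median fold was 3.01 for those that rose and 0.314 for those that fell. A fold of 10 or more was reached by 66 genes, and a fold of 0.1 or less by 153 genes.

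Adcy1, an adenylate cyclase (ENSRNOG00000059479), stood at 0.02 of the lean level in obese hearts in the authors' deposited table (adjusted p = 8.28e-120), and Fads6 at 0.021 (adjusted p = 1.52e-249). The authors' deposited table placed Ak4, a mitochondrial adenylate kinase (ENSRNOG00000045738), at 0.024, Acmsd at 0.032 and Grid1 at 0.033. Ogdh, the first subunit of the 2-oxoglutarate dehydrogenase complex (ENSRNOG00000005130), stood at 0.03, the pacemaker channel gene Hcn2 at 0.033 and Prkaa2, a catalytic subunit of AMP-activated protein kinase, at 0.036, all with an adjusted p given as 0 in the authors' deposited table. Pkia, an inhibitor of protein kinase A, at 0.036, and Jph2, which ties the sarcoplasmic reticulum to the cell membrane, at 0.043, were also given an adjusted p of 0 in the authors' deposited table.

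Hapln1, a link protein of the hyaluronan matrix (ENSRNOG00000032002), was 32 times as high in obese as in lean hearts in the authors' deposited table (adjusted p = 7.16e-19). The same authors' deposited table gave folds of 22.8 for S100a9, 22.5 for SNORA73, 22.3 for Agr2, 21.9 for both Cthrc1 and Oscar, 21.3 for Tnc and 20.3 for Mmp8. SNORA73 is a family of small nucleolar RNAs with several near-identical copies, so its value is uncertain. The smallest adjusted p-values among genes that rose belonged, in the authors' deposited table, to Arhgdib (fold 3.65, adjusted p = 5.48e-159), Nucb2 (fold 4.23), Tkt (fold 3.86), Rhog (fold 3.39) and Tgfb1 (fold 4.20).

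Genes of fuel oxidation fell. Of 24 genes for pyruvate dehydrogenase and the tricarboxylic acid cycle, 23 fell and none rose (Fisher's exact test of direction against the other listed genes, adjusted p = 8.88e-07). After Ogdh, the smallest adjusted p-values in this list belonged to Cs, the citrate synthase gene, at 0.095 of the lean level, Dlat at 0.097 and Suclg2 at 0.193 in the authors' deposited table. In the fatty acid oxidation list 13 of 21 genes fell and 0 rose (Fisher's exact test, adjusted p = 0.00032). Its leading members in the authors' deposited table were Hadhb at 0.072, Hadh at 0.053, Acsl1 at 0.171 and Cpt1b, the muscle carnitine palmitoyltransferase, at 0.213. Branched-chain amino acid catabolism showed 17 falls and 1 rise among 19 genes (Fisher's exact test, adjusted p = 0.00032). The authors' deposited table had Acadsb at 0.046, Mccc1 at 0.156 and Acad8 at 0.132, while Bcat1, the cytosolic aminotransferase, rose with a fold of 4.53.

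Genes of glucose use fell as well. Of 20 genes for glucose uptake and glycolysis, 11 fell and 0 rose (Fisher's exact test, adjusted p = 0.000984), among them Pfkm at 0.123, Hk2 at 0.287, Pkm at 0.225 and the insulin-responsive transporter gene Slc2a4 at 0.212 in the authors' deposited table. Of 7 ketone genes 6 fell and 1 rose (Fisher's exact test, adjusted p = 0.0884), which did not pass the threshold, although the list fell with cameraPR at preset correlations of 0.01 and 0.05, by ranks and on the signed logarithm of the adjusted p (adjusted p = 0.00678, 0.0176, 0.0179 and 0.0031). Bdh1 stood at 0.041, Oxct1 at 0.06 and Slc16a1, a monocarboxylate transporter, at 0.087 in the authors' deposited table. PPAR targets gave 16 falls and 3 rises among 25 genes (Fisher's exact test, adjusted p = 0.0038). Pdk4, a kinase that switches off pyruvate dehydrogenase, stood at 0.06 and Ucp3 at 0.104 in the authors' deposited table. Rises included Angptl4 with a fold of 2.36 and Fgf21 with a fold of 11.2 in the authors' deposited table. Lipid storage genes fell in 11 cases and rose in 1 among 20 (Fisher's exact test, adjusted p = 0.00588), led by Gpam at 0.095, Lpin1 at 0.063 and Plin4 at 0.054 in the authors' deposited table.

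The 3 lists for the respiratory chain and ATP synthase hold nuclear genes, while the 12 listed mRNAs of the mitochondrial genome, which encode subunits of complexes I, III and IV and of ATP synthase, all rose, with folds of 2.64 to 4.35 in the authors' deposited table. Of 37 nuclear complex I genes 8 fell, 0 rose and 29 were not listed (Fisher's exact test, adjusted p = 0.00588). Ndufs1, the largest core subunit, stood at 0.068 in the authors' deposited table, and the median fold of the 8 was 0.471. Of 27 nuclear genes of complexes II to IV 11 fell and 0 rose (Fisher's exact test, adjusted p = 0.000984), with Sdha at 0.131 and Uqcrc2 at 0.114 in the authors' deposited table. Of 21 nuclear genes of ATP synthase and nucleotide exchange 8 fell and 0 rose (Fisher's exact test, adjusted p = 0.00588), including Vdac1 at 0.209 and Atp5f1a at 0.162 in the authors' deposited table. Of the 27 fallen genes in the 3 lists, 21 encode subunits and the rest are nucleotide exchange genes or cytochrome c. The falls in this list are therefore not all of ATP synthase subunits. Where a call for ATP synthase is given below, the whole list is meant. With limma's cameraPR at a preset correlation of 0.05 the adjusted p was 0.076 for complex I and 0.0664 for the list of ATP synthase and nucleotide exchange, so these calls were lost under that setting. By ranks they were lost too (adjusted p = 0.192 and 0.0631). Mitochondrial biogenesis, dynamics and mitophagy gave 16 falls and 1 rise among 25 genes (Fisher's exact test, adjusted p = 0.000394). Dnm1l, a fission gene, stood at 0.145, the fusion genes Opa1 and Mfn1 at 0.148 and 0.219, and Ppargc1a, a coactivator of mitochondrial biogenesis, at 0.135 in the authors' deposited table, while Bnip3l rose with a fold of 2.14.

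In the sarcomere list 14 of 22 genes fell and 0 rose (Fisher's exact test, adjusted p = 0.000296), among them Pdlim5 at 0.076, Rbm20 at 0.238, Cmya5 at 0.141 and Myom1 at 0.116 in the authors' deposited table. Calcium handling and ion channel genes fell in 14 cases and rose in 2 among 24 (Fisher's exact test, adjusted p = 0.00548). Beside Jph2, the authors' deposited table had Slc8a1, the sodium-calcium exchanger, at 0.101 and Atp2a2, the calcium pump of the sarcoplasmic reticulum, at 0.084. Trdn rose with a fold of 2.83 in the authors' deposited table. The direction of listed genes also went with gene span, since 71.9% rose in the tenth with the shortest spans and 38.3% in the tenth with the longest, and 12 of 13 small nucleolar RNAs rose. In a test added after these results were seen, 0% of the sarcomere genes rose, against 21.4% to 78.6% in the central 95% of span-matched draws, and 12.5% of the calcium genes, against 18.8% to 68.8%. Fetal and hypertrophy genes gave 9 falls and 2 rises among 19 (Fisher's exact test, adjusted p = 0.0542), short of the threshold, which cameraPR passed at a preset correlation of 0.01 (0.0403) but not at 0.05 (0.0829), by ranks (0.0631) or on the signed logarithm of the adjusted p (0.495). Myh6 stood at 0.187 and Nppb, which encodes B-type natriuretic peptide, at 0.48 (adjusted p = 0.030) in the authors' deposited table. The fetal and hypertrophy list mixes genes such as Nppb with adult genes such as Myh6 and Atp2a2. Its direction therefore cannot show whether a fetal programme was raised or lowered. Nppa, Myh7 and Lepr, the leptin receptor gene, were listed in none of the 3 tables.

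Matrix and immune genes rose. All 20 listed genes of the 29 in the extracellular matrix list rose (Fisher's exact test, adjusted p = 7.4e-05), with a median fold of 4.77. In the authors' deposited table the folds were 4.72 for Sparc, 7.21 for Fn1, 20.0 for Postn, 5.10 for Col1a1 and 4.20 for Col3a1. All 16 listed genes of the 24 for inflammation rose (Fisher's exact test, adjusted p = 0.00032), among them the adhesion molecules Icam1 (fold 5.43) and Vcam1 (fold 6.23), Nfkbia (fold 5.54) and Il1b (fold 6.36) in the authors' deposited table. Antigen presentation genes rose in 8 of 21 cases with 0 falls (Fisher's exact test, adjusted p = 0.0185), and the authors' deposited table gave RT1-Db1, of the rat major histocompatibility complex, a fold of 5.46. Genes of this complex are highly similar and differ between strains, so reads may have been divided among them. Proliferation genes rose in 8 of 16 cases with 0 falls (Fisher's exact test, adjusted p = 0.0185), with folds of 4.38 for Mki67 and 4.06 for Tpx2 in the authors' deposited table. The interferon list had 6 rises and 0 falls among 20 genes (Fisher's exact test, adjusted p = 0.058).

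Markers of cell types moved with these groups, but some genes are in both kinds of list, so this is not separate support. Myh6 is in the cardiomyocyte and sarcomere lists, and Col1a1 and Col3a1 are in the fibroblast and matrix lists. S100a8 and S100a9 are in the neutrophil and inflammation lists. Cardiomyocyte markers fell in 8 of 12 cases with 0 rises (Fisher's exact test, adjusted p = 0.00588), with a median fold of 0.317. The markers that rose with 0 falls were those of macrophages in 10 of 12 cases (adjusted p = 0.00589), endothelium in 9 of 12 (adjusted p = 0.0107), fibroblasts in 7 of 12 and lymphocytes in 7 of 12 (adjusted p = 0.0326 for each, all by Fisher's exact test). Their median folds were 3.24, 3.51, 3.32 and 3.51. The endothelial, fibroblast and lymphocyte calls were lost with cameraPR at a preset correlation of 0.05 (adjusted p = 0.0664, 0.0542 and 0.051), and the fibroblast and lymphocyte calls without their most changed member (adjusted p = 0.062 for each). On the signed logarithm of the adjusted p, cameraPR gave cardiomyocyte markers an upward direction (adjusted p = 0.976) and ended that call. It also ended the calls of fibroblast (0.462), endothelial (0.089), macrophage (0.402) and lymphocyte (0.495) markers, of glycolysis (0.191), complex I (0.62), complexes II to IV (0.402), ATP synthase (0.655), antigen presentation (0.402) and proliferation (0.495). The 4 listed neutrophil markers rose with a median fold of 20.1, too few for the direction test to pass (Fisher's exact test, adjusted p = 0.175), although they passed with cameraPR at preset correlations of 0.01 and 0.05 and by ranks (adjusted p = 0.000164, 0.000859 and 0.00278), but not on the signed logarithm of the adjusted p (0.402). S100a8 had a fold of 20.0 and Csf3r, the granulocyte colony-stimulating factor receptor gene, one of 10.3 in the authors' deposited table.

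**Figure D1:**
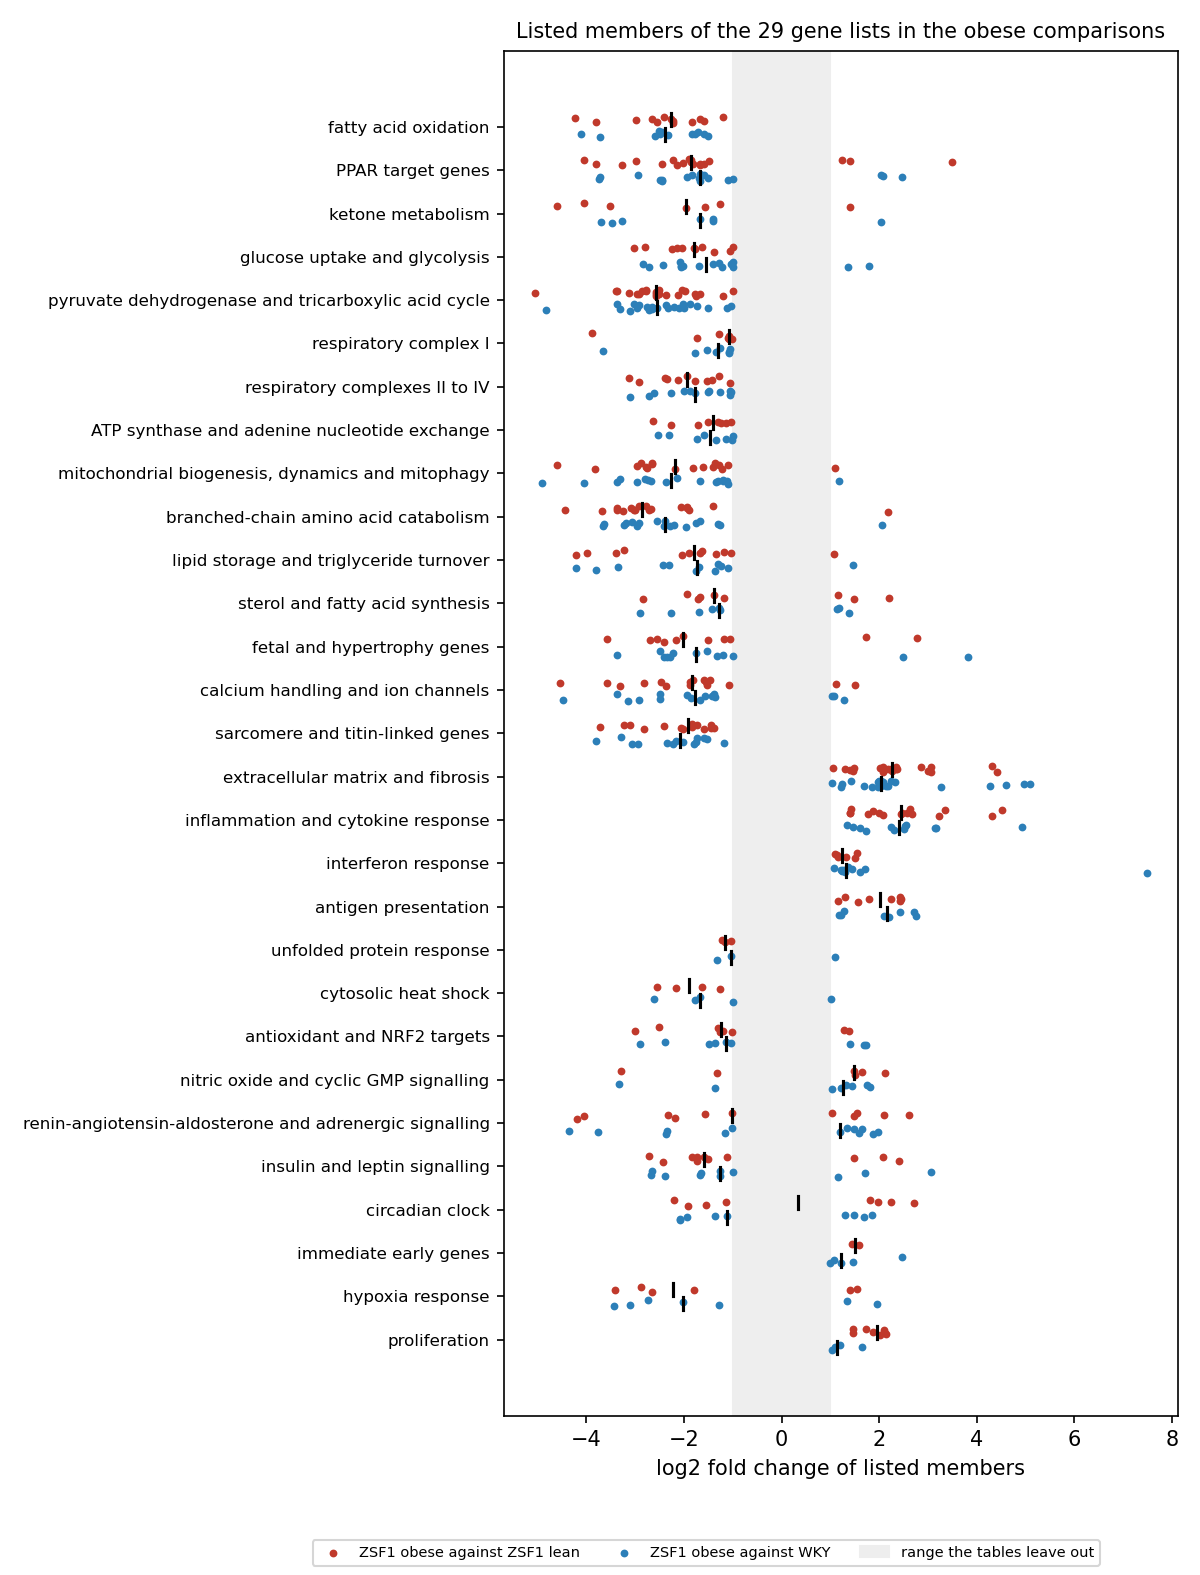
Log2 fold changes (x axis) of listed members of the 29 gene lists (rows), with red points for ZSF1 obese against ZSF1 lean, blue points for ZSF1 obese against WKY and black bars for medians; each point is 1 gene, and the grey band is the range the tables leave out. All 23 listed genes of the tricarboxylic acid cycle list lie left of the band or on its edge in obese against lean, and all 20 listed matrix genes lie right of it.

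**Figure D2:**
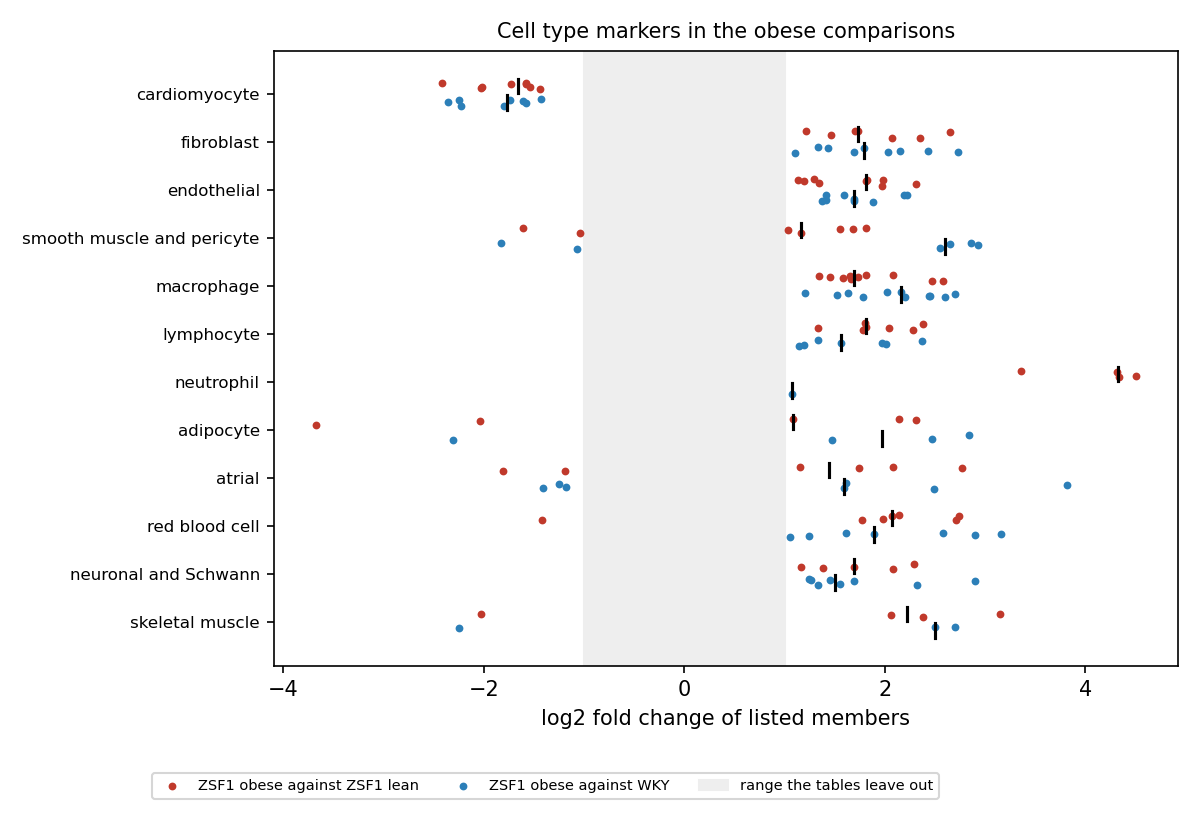
Log2 fold changes (x axis) of listed markers of 12 cell types (rows), with the same colours, bars and grey band as for the gene lists; each point is 1 gene. The 8 listed cardiomyocyte markers lie on the left in both comparisons, and 4 neutrophil markers lie far to the right in obese against lean, against 1 listed in obese against WKY.

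The second comparison, ZSF1 obese against WKY, sets the disease model against the control strain, so that strain and disease differ together. The authors' deposited table held 5709 genes, with 3084 higher and 2625 lower in the obese hearts. All listed members fell for pyruvate dehydrogenase and the tricarboxylic acid cycle (23 of 24 genes, Fisher's exact test, adjusted p = 6.58e-07), fatty acid oxidation (12 of 21, adjusted p = 0.000503), nuclear genes of complexes II to IV (13 of 27, adjusted p = 0.000269), and the sarcomere (14 of 22, adjusted p = 0.000247). Branched-chain amino acid catabolism and mitochondrial biogenesis each had 17 falls and 1 rise (adjusted p = 0.000266 for both), PPAR targets 15 falls and 3 rises (adjusted p = 0.0053), lipid storage 11 falls and 1 rise (adjusted p = 0.0053) and calcium handling 13 falls and 3 rises (adjusted p = 0.0107, all by Fisher's exact test). Ketone genes had 6 falls and 1 rise, short of the threshold (Fisher's exact test, adjusted p = 0.0854). With cameraPR the ketone list passed at a preset correlation of 0.01 (adjusted p = 0.0247) but not at 0.05 (0.0508) or by ranks (0.0597). Extracellular matrix genes rose in 21 of 29 cases (adjusted p = 8.75e-05), inflammation genes in 12 of 24 (adjusted p = 0.00347) and antigen presentation genes in 8 of 21 (adjusted p = 0.0167), with 0 falls in each, by Fisher's exact test. In gene families chosen after the data had been read, mitochondrially encoded mRNAs rose in 11 of 11 listed cases (adjusted p = 0.00236) and small nucleolar RNAs, which lack a poly(A) tail, in 14 of 14 (adjusted p = 0.000628, both by Fisher's exact test). In all, 24 of 40 lists passed against WKY, 14 of which fell and 10 rose, and 21 passed against lean hearts, 13 of which fell and 8 rose. Lists that share genes were counted separately.

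In obese against WKY hearts, Ak4 stood at 0.021 of the WKY level (adjusted p = 8.80e-71), Rims1 and Myo3b at 0.024, Adcy1 at 0.025, Zim1 and Fads6 at 0.026, Atp1a4 at 0.027 and Prkaa2 at 0.029 in the authors' deposited table. Prkaa2, Ogdh at 0.035, Pdk2 at 0.041 and Hadhb at 0.076 had an adjusted p given as 0, and Tead1, a transcription factor gene, stood at 0.052 (adjusted p = 7.21e-286) in the authors' deposited table. Ppargc1a stood at 0.097, Pdk4 at 0.075, Atp2a2 at 0.097, Slc2a4 at 0.238, Cpt1b at 0.182 and Bdh1 at 0.09 in the authors' deposited table.

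Among the genes that rose, Ifit1, an interferon-induced gene (ENSRNOG00000019050), was 180 times as high in obese as in WKY hearts (adjusted p = 3.83e-72) and Tcp11x2 (ENSRNOG00000011034) 174 times as high (adjusted p = 4.13e-110) in the authors' deposited table. Setd4 had a fold of 94.4, Cdh26 of 69.1, RT1-S2 of 50.2, Sez6l of 48.8, Trh of 45.3 and Thbs4 of 34.3 in the authors' deposited table. Of these 8 genes, Ifit1, Tcp11x2, Setd4, Cdh26, RT1-S2 and Sez6l also rose in lean hearts against WKY. By adjusted p, the leading rises in the authors' deposited table were Arhgdib (fold 4.06), Fcgrt (fold 5.03), Tcp11x2, Klf4 (fold 5.54) and Castor1 (fold 5.13).

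Several lists stood on the other side of the threshold than against lean hearts, a difference that was not itself tested. The interferon list had 10 rises and 0 falls among 20 genes (Fisher's exact test, adjusted p = 0.0063, but 0.137 with cameraPR by ranks and 0.0812 with cameraPR on the signed logarithm of the adjusted p), and the fetal and hypertrophy list 11 falls and 2 rises among 19 (adjusted p = 0.0167, Fisher's exact test). In that list Myl7, an atrial myosin light chain gene, had a fold of 14.1 and Nppb stood at 0.297 in the authors' deposited table. Here too, the direction of this mixed list cannot show whether a fetal programme was raised or lowered. Red blood cell markers rose in 7 of 10 cases (adjusted p = 0.0295) and neuronal and Schwann cell markers in 8 of 12 (adjusted p = 0.0167), with 0 falls in each, by Fisher's exact test. The red blood cell call was lost without the most changed member (adjusted p = 0.0542). Proliferation genes had 4 rises and 0 falls among 16 (Fisher's exact test, adjusted p = 0.185). With cameraPR at a preset correlation of 0.05, the adjusted p was 0.10 for the fetal and hypertrophy list and 0.073 for the neuronal and Schwann list. That setting also ended the calls for glycolysis, which had 14 falls and 2 rises among 20 genes (Fisher's exact test, adjusted p = 0.00347, and 0.0552 with cameraPR), and for complex I, which had 8 falls and 0 rises (Fisher's exact test, adjusted p = 0.0053, and 0.0702 with cameraPR). The list of ATP synthase and nucleotide exchange genes gave the same 8 falls and 0 rises with the same adjusted p-values in both tests, and 3 of the 8 encode ATP synthase subunits. By ranks, cameraPR also ended the calls for complex I (adjusted p = 0.112), ATP synthase (0.0766), the fetal and hypertrophy list (0.0638), and neuronal and Schwann markers (0.0655). On the signed logarithm of the adjusted p it ended those for glycolysis (0.302), complex I (0.665), complexes II to IV (0.316), ATP synthase (0.456), the fetal and hypertrophy list (0.302), antigen presentation (0.316), and red blood cell (0.302) and neuronal and Schwann (0.302) markers.

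Among cell types, cardiomyocyte markers fell in 8 of 12 cases against WKY (adjusted p = 0.0053), and markers of macrophages rose in 11 of 12 (adjusted p = 0.0053), of endothelium and of fibroblasts in 9 of 12 each (adjusted p = 0.0107 for both) and of lymphocytes in 7 of 12 (adjusted p = 0.0295), all by Fisher's exact test. With cameraPR at a preset correlation of 0.05 the endothelial, fibroblast and lymphocyte calls were lost (adjusted p = 0.0685, 0.0508 and 0.10). The lymphocyte call was also lost by ranks (adjusted p = 0.0883), at a preset correlation of 0.01 (0.0628) and without the most changed member (0.0542). On the signed logarithm of the adjusted p, cameraPR ended the calls of cardiomyocyte (0.871), fibroblast (0.316), macrophage (0.186) and lymphocyte (0.484) markers. Smooth muscle and pericyte markers had 4 rises and 2 falls among 12 (Fisher's exact test, adjusted p = 0.77; cameraPR at 0.05, adjusted p = 0.224), with folds of 7.62 for Cnn1, 7.26 for Tagln, 6.28 for Myh11 and 0.281 for Des in the authors' deposited table. Csf3r, with a fold of 2.1 in the authors' deposited table, was the single neutrophil marker listed.

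The third comparison, ZSF1 lean against WKY, concerns the hypertensive strain without obesity. The authors' deposited table held 233 genes, 149 higher and 84 lower in the lean hearts. No gene of the fatty acid oxidation, tricarboxylic acid cycle, respiratory chain, sarcomere or extracellular matrix lists was among them. Plppr4 had the largest fold, 17.5 (adjusted p = 4.49e-73), followed in the authors' deposited table by Ifit1 at 15.1, Tcp11x2 at 14.8, Setd4 at 8.00, Frmpd1 at 7.89, Trim16 and Vwa2 at 7.36 and Pbld1 at 7.21. The sizes of these folds are uncertain, because the 2 obese comparisons imply larger lean changes for some of them. For Plppr4 the listed log2 change was 4.13 and the implied one 6.69, and for Setd4 they were 3.00 and 5.00. Ifit1 was not listed in obese against lean, so no lean change is implied for it. The gene listed as Trim16 (ENSRNOG00000003287) carries the description F-box and WD repeat domain containing 10, so its name is uncertain. Eno1, the glycolytic enolase gene, had the smallest adjusted p (fold 5.17, adjusted p = 6.61e-300), and Ephx2, a soluble epoxide hydrolase gene, a fold of 3.32 in the authors' deposited table. Ace, the angiotensin-converting enzyme gene, had a fold of 5.43 and Bdh1 one of 2.16 in the authors' deposited table.

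Falls in lean hearts were smaller. Egfl6 stood at 0.19 of the WKY level, Ifi44l at 0.24, Klhdc8a and RT1-N2 at 0.25, Ccdc68 at 0.27, Pus7l at 0.28 and Tdrd1 and Vxn at 0.29 in the authors' deposited table. By adjusted p the leading falls there were Tom1l1 at 0.37 (adjusted p = 2.54e-59), Tdrd1, Pus7l, Kyat1 at 0.49 and Aldh1a1 at 0.50 in the authors' deposited table. The neutrophil markers Csf3r and S100a9 stood at 0.33 and Mmp8 at 0.35 in the authors' deposited table (3 falls and 0 rises, Fisher's exact test, adjusted p = 0.0916). With cameraPR they passed at preset correlations of 0.01 and 0.05 and by ranks (adjusted p = 0.0274, 0.035 and 0.0208), but not on the signed logarithm of the adjusted p (0.758). This list is not of the same stringency as the other 2, since its largest adjusted p was 0.000347, against 0.0498 and 0.0499 in the obese lists. With the obese lists held to that same limit, 5060 and 5021 genes remained. This does not make the lists alike. Lean changes were smaller than the obese lists imply in all 79 genes listed in every comparison, so the same fold limit may be stricter for the lean list.

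Set side by side, both obese comparisons listed 4847 genes, of which 2523 rose in both, 2314 fell in both and 10 moved in opposite directions. Their log2 fold changes correlated across these genes with r = 0.969 (genes are not independent replicates), and their difference had a median of 0.00 and an SD of 0.50. Both comparisons use the same 6 obese hearts. Over all 6562 simulated genes, unchanged groups that share 1 group of 6 gave r = 0.494. The direction was the same in 66.8% of these genes and in 97.7% of those in the largest 20% of changes in both. The observed r covers only genes that passed the fold limit in both tables, and no simulated r was computed for genes so selected. Leaving out small changes can itself raise r, so 0.494 is not a like value to set beside 0.969. Independent lists drawn from the 6562 genes listed in either comparison would share 1431 rises and 1062 falls. The number of genes the authors tested is not given, and a larger number would lower these values. Part of the overlap may come from the shared obese hearts.

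**Figure D3:**
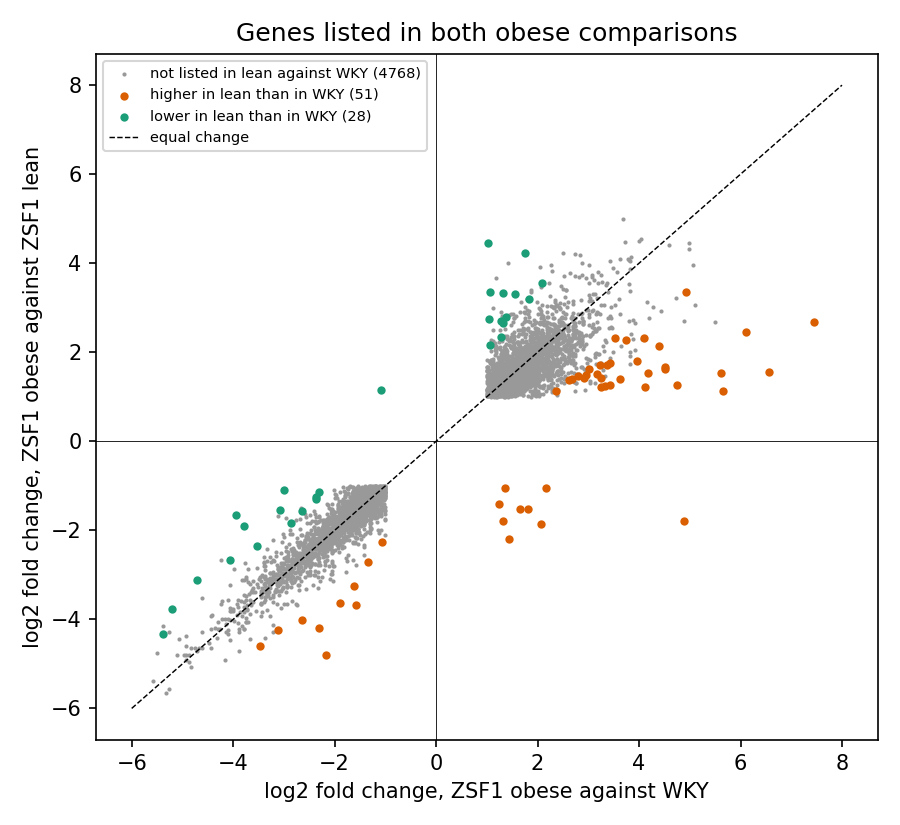
Log2 fold changes against WKY (x axis) and against ZSF1 lean (y axis) for the 4847 genes listed in both obese comparisons; each point is 1 gene, coloured where the gene was also higher (51) or lower (28) in lean than in WKY hearts, and the dashed line marks equal change. Of 4768 uncoloured genes, 156 lie more than 1 log2 unit off the line, as do 79 of the 79 coloured genes.

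For the 5709 genes that differed between obese and WKY hearts, the tables show at which step the change was listed. Of these, 4791 genes (83.9%) were listed with the same direction between lean and obese hearts alone, 83 genes (1.45%) between WKY and lean hearts alone, 46 genes at both steps and 789 genes (13.8%) at neither. Spp1, which encodes osteopontin, rose at both steps, with a fold of 2.35 in lean against WKY, 10.2 in obese against lean and 30.5 in obese against WKY in the authors' deposited table. The lean list limits this count. For the 79 genes present in all 3 tables, the lean change implied by the obese tables always had the listed sign, but the listed log2 change was smaller in 79 of 79, with a median ratio of 0.794.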

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

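The genes described here were picked out after the tables had been read. In all, 23 genes moved one way in lean hearts and the other way in obese hearts, both against WKY, and each of them was also listed in the direct comparison of obese with lean hearts. That listing follows largely from the choice of genes with opposite changes of at least 2-fold against the same WKY hearts, so it is not independent evidence. Of these, 10 rose in lean and fell in obese hearts, and 13 fell in lean and rose in obese hearts.

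Bdh1, the mitochondrial enzyme that interconverts ketone bodies, had a fold of 2.16 in lean and 0.09 in obese hearts against WKY, and 0.041 in obese against lean (adjusted p = 1.53e-117), in the authors' deposited tables. Csf3r, a neutrophil marker, had folds of 0.33, 2.1 and 10.3 in the same order (adjusted p = 5.42e-22 for obese against lean). Oscar, a receptor of myeloid cells, had 0.33, 2.04 and 21.9 (adjusted p = 5.44e-14), and Epb42, of the red cell membrane, 0.43, 2.07 and 6.68 (adjusted p = 1.05e-11). In obese against WKY the folds of Csf3r, Oscar and Epb42 were close to the limit of 2. Their adjusted p-values there were 0.000598, 0.0213 and 0.00143 in the authors' deposited table. For Oscar the listed lean log2 change was -1.60 and the implied one -3.42. Slc4a1, another red blood cell marker, moved against Epb42. It had a fold of 5.5 in lean against WKY and a log2 change of -1.42 in obese against lean. Maoa, which breaks down monoamines and was named after its values were seen, had folds of 3.01 in lean and 0.337 in obese hearts against WKY. Its fold was 0.078 in obese against lean.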

How the results depend on the processing

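An adjusted p of 0.01 in place of 0.05 left the 3 gene counts, the overlap and the step count within 1.5 times their values, as did regular gene names for the gene counts; a log2 change of at least 1 removes no gene, because the tables start there. Settings added after seeing the data moved more. A fold of at least 4 left 1709 genes in obese against lean, 1793 in obese against WKY, 24 in lean against WKY and 1259 genes shared in direction by the obese comparisons, as a stricter limit must. The signed logarithm of the adjusted p in cameraPR called 11 lists in place of 21 in obese against lean and 12 in place of 24 in obese against WKY; the cause was not tested. The calls it ended in both comparisons were those for glycolysis, complex I, complexes II to IV, ATP synthase, antigen presentation and the markers of cardiomyocytes, fibroblasts, macrophages and lymphocytes. It also ended proliferation and endothelial markers against lean hearts, and the fetal and hypertrophy, interferon, red blood cell and neuronal and Schwann lists against WKY. The other list settings called 18 to 25 lists and 16 to 24 lists, and no list changed direction while passing the threshold. Lymphocyte markers against WKY were lost with cameraPR at 0.01, with an adjusted p of 0.01 for genes and without their most changed member, which also ended the calls for red blood cell markers against WKY and for fibroblast and lymphocyte markers against lean hearts. Not run, for want of mean levels, standard errors, unadjusted p-values or unlisted genes, were an adjusted p of 0.1, a log2 change of 0.5, minimum mean levels, recomputed or Bonferroni adjustment, recentring, cameraPR on the Wald statistic, and the tests of the derived lean change. Regrouping the rats was not possible either, so protection against chance rests on the authors' test. Depth is unknown and limits which genes could be listed.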

Other observations

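The test of shrunken lean folds was set down before its result was seen. All other tests here, those of gene span included, and the gene families are treated as chosen after the data had been read. Transcripts of the mitochondrial genome moved against the nuclear genes of the same organelle. In obese against lean hearts, 12 of 12 listed mitochondrially encoded mRNAs rose, with folds of 2.64 to 4.35 (Fisher's exact test of direction, adjusted p = 0.00128 over 16 tests of gene families). Mitochondrial ribosomal protein genes fell in 25 of 25 cases (adjusted p = 1.91e-08) and import genes of the Timm and Tomm families in 10 of 10 (adjusted p = 0.00109). Cytosolic ribosomal protein genes rose in 51 of 52 cases, with a median fold of 2.59 (adjusted p = 6.79e-12), and the exception was Rpl3l, a striated muscle paralog, at 0.261 in the authors' deposited table. Against WKY 43 of them rose and 2 fell. The gene families of this paragraph and the matrix and immune lists were not set against span-matched draws. A link of their direction with gene span therefore stays open. Keratin genes rose in 9 of 9 cases (adjusted p = 0.00606) and Hox genes in 6 of 6 (adjusted p = 0.0356). Proteasome subunit genes had 7 falls and 1 rise (adjusted p = 0.0332), and 8 falls and 2 rises against WKY (adjusted p = 0.0516).

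Clock genes went both ways (4 rises and 4 falls in obese against lean, Fisher's exact test, adjusted p = 1.00). That test looks for 1 shared direction. It cannot show an ordered change in which some members rise while others fall, so it does not speak against a change of the clock. In the authors' deposited table Ciart had a fold of 6.59, Dbp of 4.76, Per3 of 3.94 and Per2 of 3.53, and Arntl stood at 0.218, Bhlhe41 at 0.344 and Nfil3 at 0.454. Insulin signalling genes had 8 falls and 3 rises (adjusted p = 0.175), with Akt2 at 0.186 and Insr at 0.152 in the authors' deposited table. No other list not yet described passed Fisher's test in obese against lean: sterol and fatty acid synthesis (3 rises, 6 falls), unfolded protein response (0, 3), heat shock (0, 4), antioxidant genes (2, 6), nitric oxide signalling (4, 2), renin-angiotensin and adrenergic genes (5, 6), hypoxia response (2, 4), immediate early genes (2, 0, not tested), and markers of smooth muscle (5, 2), adipocytes (3, 2), atrium (4, 2), red blood cells (6, 1, passed with cameraPR at 0.01 and by ranks, adjusted p = 0.042 and 0.013, not at 0.05 or on the signed logarithm of the adjusted p, 0.076 and 0.432), neurons and Schwann cells (5, 0) and skeletal muscle (3, 1).

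The fall of cardiomyocyte markers beside the rise of markers of other cells could reflect a lower share of cardiomyocyte RNA. Of the listed mitochondrially encoded mRNAs 100% rose, although heart muscle is their main source, which a lower share alone would not give. Their rise may itself be technical, as set out below, so it cannot decide whether a lower share is the whole cause. A lower share would raise all other cell types alike, and in obese against lean hearts the medians of 8 other cell types lay further apart than in shuffled markers (permutation p = 0.00347). That spread rests on 4 neutrophil markers, and 3 neutrophil markers were lower in lean than in WKY hearts, so part of it lies in the lean hearts. Without neutrophils the spread of medians was not beyond chance (permutation p = 0.109), nor was it in obese against WKY, where 1 neutrophil marker was listed and 7 other cell types were compared (permutation p = 0.125). These tests cannot show that the other types rose alike. They use only markers past the fold limit, which draws medians of rising markers together, and they treat markers as independent. Some listed markers also fell in obese against lean, 2 of smooth muscle and pericytes beside 5 rises and 2 of adipocytes beside 3 rises. A lower cardiomyocyte share therefore stays open for the types other than neutrophils, together with larger numbers of those cells in the obese hearts, which was not tested.

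The opposite movement of nuclear and mitochondrially encoded genes may have technical sources. Recovery that depends on gene span is a candidate for part of it: the share of listed genes that rose went from 71.9% in the tenth with the shortest spans to 38.3% in the tenth with the longest, and the fallen genes of the 3 respiratory chain and ATP synthase lists had a median span of 11.4 kb against 6.64 kb for unlisted ones (permutation p = 0.00735). Among subunits alone, without nucleotide exchange genes and cytochrome c, the medians were 9.57 kb and 6.7 kb (permutation p = 0.0626), which leaves a link with span in the subunits open. As the whole cause, recovery by gene span is argued against by 101 listed genes of 8 mitochondrial lists, of which 2.97% rose, against 44.6% to 63.4% in the central 95% of span-matched draws. Gene span includes introns, so these draws do not test recovery that depends on transcript length. Lower RNA quality or less selective poly(A) capture in the obese libraries stays open, as 92.3% of 13 listed small nucleolar RNAs, which lack a poly(A) tail, rose (exact binomial p = 0.00433), and so does an effect of the disease, which the design does not separate from any difference between the libraries. The binomial test set these RNAs against the 53.4% of all listed genes that rose. It made no allowance for gene span, so it is weak support for poly(A) capture.

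The small size of the lean list may in part be a matter of scale. If lean folds had been shrunken towards 1, the ratio of listed to implied log2 change would be lower for genes with weaker adjusted p-values. Across the 79 genes in all 3 tables this ratio was under 1 in 79 and rose with the strength of the adjusted p (Spearman rho = 0.542, Pearson r = 0.308, permutation p for rho = 1e-05, the smallest that the resamples can give; genes are not independent replicates). This is consistent with shrinkage in the lean table, and a different fit for that table is not excluded.

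As a hypothesis, Ak4, which lies 3 protein-coding genes from Lepr, may be changed by variants linked to the Lepr mutations of the obese rats. Of 100 protein-coding neighbours of Lepr, 25% were listed in obese against lean, against 22.8% of other protein-coding genes (Fisher's exact test, p = 0.632), which leaves a linked effect on single genes open.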
